A study of Mus musculus with 8 samples.

How the data were processed

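Total RNA from the prostates of 8 male C57BL/6 mice was measured on 1 array each. Per the labels' protocols, the tissue was frozen in an RNA stabilizing solution, RNA was extracted with a column kit, and cDNA was biotinylated, fragmented and hybridised to an Affymetrix mouse whole-transcript array. The authors deposited log2 probe set values for the 8 arrays, and the submitters' processing notes name Partek with no version. The background correction, the probe set summary and the normalization are not given in the sources used here. The medians of the deposited log2 values lay between 4.65 and 4.79 and the maxima between 13.2 and 13.3, so the values were used as deposited.

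The table held 41345 probe sets. The platform annotation listed 23521 of them with 1 gene symbol and 1820 with several, and 16004 were not listed there and are unnamed here. The gene IDs of 23328 single-gene probe sets were found in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. No coordinates were used, since the sources name no build for the array. Where a gene had several single-gene probe sets (1082 genes), the one with the highest mean over the 8 arrays stood for it, which gave 22180 genes. Genes with a mean under the 25th percentile (3.82 on the log2 scale) were left out, and 16635 genes were tested. Probe sets with several symbols were not named, and Pten and Ar, which had no single-gene probe set, were not analysed here.

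The 3 arrays of the high-fat diet group and the 5 arrays of the high-fat diet group with antibiotics were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no covariate). All differences are antibiotics minus high-fat diet alone, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with 0.05 as the threshold. A descriptive count took genes at an unadjusted p under 0.05 with at least a 1.5-fold difference. Exact two-sided permutation tests of single genes used all 56 splits of the 8 arrays into 3 and 5, so the smallest p they can give is 0.0179. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, for 46 lists written before the data were examined, and again with an estimated correlation and with fry. The values of a list per array are the means of its members' log2 values, each member centred on its own mean over the 8 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

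The rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule took 12 genes higher and 12 lower with antibiotics. Genes past the adjusted threshold whose groups did not overlap came first, and the remaining places went to the smallest unadjusted p among genes with at least a 1.5-fold difference and no overlap. Predicted genes, microRNAs, small nucleolar RNAs and small nuclear RNAs were counted but not taken. At most 4 members of each list were added, and Igf1, Igf2, Igf1r, Pten, Ar, Mki67, Il6, Ffar2, Ffar3, Krt8 and Pbsn in any case. The IGF axis list was written with knowledge of the study's interest in Igf1, so it is not independent evidence of a direction.

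The steps were tested on simulated arrays of the same size, with 200 of 16635 genes changed in each of 20 runs and genes drawn independently. The limma step recovered 45.6% of genes changed 1.5-fold, 82.3% of those changed 2-fold and 97.7% of those changed 4-fold, and 5.445% of its calls were false. The camera step called a list shifted by 0.3 in 20 of 20 runs and 4 of 900 unshifted lists. Simulated genes were not correlated, so this last share does not hold for lists whose genes move together. The shares of genes recovered and of false calls rest on the same independent genes and may not carry over to the real arrays. Other splits of the real arrays gave up to 152 genes past the adjusted threshold, against 1 for the real groups.

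The alternatives were quantile normalization, centring each array on its median, other filters on dim genes, the mean of all probe sets of a gene, eBayes with trend and robust, array quality weights, a linear model without moderation, the replicate number as a block, a looser threshold and leaving out each array in turn. With trend and robust, camera used the trend only, and the unmoderated statistics of lists went through camera's preranked form. Fits with the seminal vesicle and skeletal muscle lists, or the fibroblast and matrix list, as covariates, and fits without the arrays highest or lowest in them, were added after the data were seen. Gene families were also looked through by name after the data were seen, and their p-values were adjusted over the 20 sets tested this way. With 3 and 5 mice, the number of arrays limits the precision: the median standard error of a log2 difference was 0.122.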

Results

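Prostate expression was measured in 8 mice of a prostate cancer model, 3 on a high-fat diet alone and 5 on the same diet with antibiotics, with 1 array per mouse. All were males of the genotype Pb-Cre+; Pten(fl/fl), in which Cre recombinase under the probasin promoter removes the tumour suppressor Pten from prostate epithelium. The mice were 5 weeks old when the diet began and 22 weeks old when the tissue was taken. The antibiotic mixture held ampicillin at 0.2 g/L, vancomycin at 0.1 g/L and metronidazole at 0.2 g/L. For neomycin the labels give 0.2, 0.3, 0.4, 0.5 and 0.6 g/L for replicates 1 to 5 in that order. These rise by the same step with the replicate number, so they may not be the doses given, and no relation of expression to them was tested. The comparison asks how prostate expression under a high-fat diet differed when gut bacteria were depleted, with the insulin-like growth factor (IGF) axis as an interest of the study. Any 2 arrays correlated at 0.971 to 0.984 over all probe sets, so no array was a copy of another.

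Epyc, which encodes epiphycan, a small leucine-rich proteoglycan of cartilage matrix, fell with antibiotics. Its log2 value was 7.89 ± 0.26 (SD, n = 3) on the diet alone and 6.38 ± 0.14 (SD, n = 5) with antibiotics, which is 2.85-fold lower (log2 difference -1.51, SE 0.13, limma adjusted p = 0.0136). All 5 antibiotic arrays lay below all 3 others. It was the 1 gene of 16635 past the adjusted threshold, and 0 genes rose in limma's test. The next smallest adjusted p was 0.673. At an unadjusted p under 0.05 there were 1216 genes, 760 higher and 456 lower, against 831.8 expected by chance. The spread around that number was wide. Of the 56 splits of the arrays into 3 and 5, 8 gave at least 1216, the real one included. Splits other than the real one ran from 330 to 2423. Of the 1216, 127 differed at least 1.5-fold, 49 higher and 78 lower, and the lean to lower genes was not stable: it was 54 higher and 52 lower without antibiotic replicate 3, and 59 and 54 without antibiotic replicate 5. The groups did not overlap for 851 genes (5.12%), against 3.57% by chance. The linear model without moderation called 0 genes and gave Epyc an adjusted p of 0.271. Without high-fat diet replicate 2 or antibiotic replicate 4, Epyc stayed past the threshold (adjusted p = 0.0185 and 0.0453). It did not without high-fat diet replicate 1 (0.171) or 3 (0.0526) or antibiotic replicate 1 (0.0614), 2 (0.0629), 3 (0.0866) or 5 (0.0605). Its log2 difference was -1.38 to -1.64 over these 8 fits, and its adjusted p ran from 0.00599 to 0.991 over all alternatives.

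**Figure D1:**
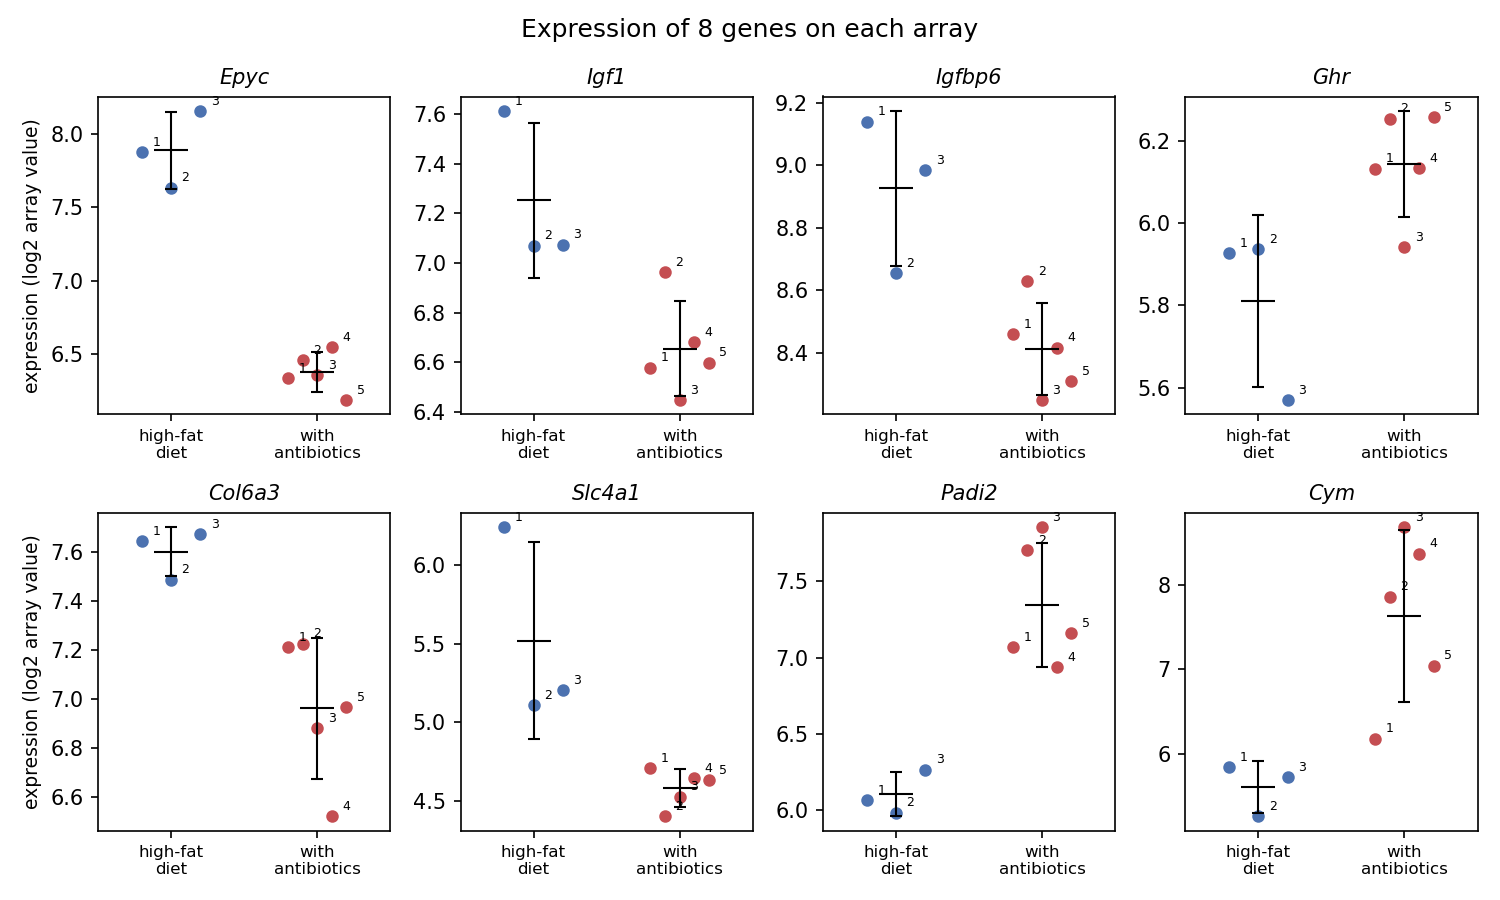
Log2 array values of 8 genes on each array (points, numbered by replicate), by group, with the mean and SD as bars; the vertical axes do not start at 0. For Epyc, the 5 antibiotic arrays lay at 6.19 to 6.54 and the 3 high-fat diet arrays at 7.63 to 8.16.

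The other genes named by the rule did not pass the adjusted threshold (adjusted p = 0.673 each). The rule took only genes whose groups did not overlap, so that trait is no evidence for them. Among the 12 that were higher with antibiotics, Cym, which encodes the milk-clotting protease chymosin, had the largest difference (log2 2.02, SE 0.51) and varied most (7.63 ± 1.02, SD, n = 5, against 5.61 ± 0.31, SD, n = 3). Padi2, whose enzyme converts arginine to citrulline in proteins, was 2.36-fold higher (log2 1.24, SE 0.21), but a second, dimmer probe set of Padi2 gave only 0.10. Cyp4f39, a fatty acid hydroxylase of the cytochrome P450 family, was 1.94-fold higher (log2 0.96, SE 0.16). The monocarboxylate transporter family member Slc16a12 and Dapl1 were higher by 0.89 and 0.90 on the log2 scale. Zfp773, Car8, Rgs13, Myo1a, Fras1, Angpt1 and Ugt2b35 were higher by 0.64 to 0.76, and the second probe set of Angpt1 gave 0.15. Among the lower genes, the olfactory receptor Olfr726 differed by -1.09 (SE 0.25). Slc4a1, the anion exchanger of red cells, differed by -0.94 (SE 0.23), with 5.52 ± 0.63 (SD, n = 3) on the diet alone and 4.58 ± 0.12 (SD, n = 5) with antibiotics, and by -0.57 without high-fat diet replicate 1. Podxl, a sialomucin of podocytes and endothelium, and Fxyd1, a regulator of the sodium pump, both differed by -0.78. P2ry14, a receptor for UDP-glucose, differed by -0.73, Mfsd2a, a transporter of lysophospholipids, by -0.69, and Ang4, an antimicrobial ribonuclease, by -0.68. Plac8, Unc5a, Col6a3 and Cdc25c differed by -0.67, -0.66, -0.64 and -0.59.

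Within the IGF axis, the growth factor Igf1 and the binding protein Igfbp6 were the members with the smallest p, and both were lower on all 5 antibiotic arrays than on any other array. Igf1 was at 7.25 ± 0.31 (SD, n = 3) on the diet alone and at 6.65 ± 0.19 (SD, n = 5) with antibiotics, a 1.51-fold lower level (log2 difference -0.60, SE 0.16, exact permutation p = 0.0179). Igfbp6 was 1.43-fold lower (log2 difference -0.51, SE 0.13, exact permutation p = 0.0179). The growth hormone receptor gene Ghr was higher by 0.33 (SE 0.12) and Igfbp3, which encodes a major carrier of IGF1, by 0.50 (SE 0.23). Ghr was at 0.21 without high-fat diet replicate 3 and Igfbp3 at 0.31 without high-fat diet replicate 2. None of the 4 passed over all genes (adjusted p = 0.673 each). When p-values were adjusted over the list alone, 2 of the 18 members passed, Igf1 and Igfbp6 (0.0356 each), and 0 passed over all genes in limma, against 3 at an unadjusted p under 0.05 and 0 without moderation. The list was chosen with the study's interest in Igf1 in mind, so this count is not independent evidence. The receptor gene Igf1r differed by -0.24 (SE 0.13, adjusted p = 0.699), or by -0.07 without high-fat diet replicate 2, and Igf2 by -0.07 (SE 0.18, adjusted p = 0.937), or by 0.09 without high-fat diet replicate 3. As a whole the list did not stand apart, with 8 members higher and 10 lower (camera adjusted p = 0.519).

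Of the 46 gene lists, 6 passed camera's threshold at its preset correlation, all lower with antibiotics. Markers of fibroblasts and matrix were lower for 15 of 16 genes, by -0.27 on average (adjusted p = 0.000294; adjusted p = 0.999577 with an estimated correlation, unadjusted 0.176). Col6a3, a chain of collagen VI, was 1.56-fold lower, the matrix proteoglycan gene Lum differed by -0.73 (SE 0.25), the matricellular protein gene Postn by -0.59 (SE 0.24) and Fap, a protease of activated fibroblasts, by -0.40 (SE 0.19). Col6a3 was the 1 member that passed when adjusted over the list alone (0.0451), and 0 passed over all genes in limma, against 3 at an unadjusted p under 0.05 and 0 without moderation. Contractile genes of smooth muscle were lower for 11 of 11, by -0.40 on average (adjusted p = 0.0105; adjusted p = 0.999577 with an estimated correlation, unadjusted 0.327), among them Des at -0.63 (SE 0.55), Actg2 at -0.51 (SE 0.43), Tagln at -0.41 (SE 0.29) and Acta2 at -0.35 (SE 0.30). Without high-fat diet replicate 2 these 4 were at -0.14, -0.08, -0.13 and -0.09. Endothelial markers were lower for 11 of 12, by -0.15 on average (adjusted p = 0.00953; adjusted p = 0.999577 with an estimated correlation, unadjusted 0.212), with Tie1 at -0.29 (SE 0.17), Egfl7 at -0.28 (SE 0.15) and Robo4 at -0.21 (SE 0.12), and with Tie1 at -0.18 without antibiotic replicate 5. The members named here had adjusted p-values of 0.673 to 0.780 over all genes.

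Interferon-stimulated genes were lower for 19 of 20 members, by -0.34 on average (adjusted p = 0.000277; adjusted p = 0.999577 with an estimated correlation, unadjusted 0.274). The chemokine gene Cxcl10 differed by -0.65 (SE 0.43) and the antiviral genes Oasl1, Dhx58 and Oas2 by -0.59, -0.40 and -0.37 (adjusted p = 0.704 to 0.736), and without high-fat diet replicate 1 the 4 differed by -0.14, -0.26, -0.21 and -0.13. The list's level varied by 1.28 on the log2 scale between arrays, with high-fat diet replicates 1 and 2 at 0.66 and 0.49 and high-fat diet replicate 3 at -0.51. Mitotic genes were lower for 17 of 25, by -0.12 on average (adjusted p = 0.00168; adjusted p = 0.999577 with an estimated correlation, unadjusted 0.294). The anaphase ubiquitin-conjugating enzyme gene Ube2c differed by -0.39 (SE 0.11), Ccna2, which encodes cyclin A2, by -0.39 (SE 0.14), and the mitotic kinase gene Aurkb and the kinesin gene Kif20a by -0.31 each (adjusted p = 0.673 each). Without high-fat diet replicate 2, Ccna2 differed by -0.25 and Kif20a by -0.18. Mki67, a marker of cycling cells, was higher by 0.12 (SE 0.11, adjusted p = 0.802), and at -0.01 without high-fat diet replicate 1. Target and feedback genes of ERK signalling were lower for 13 of 16, by -0.10 on average (adjusted p = 0.0415; adjusted p = 0.999577 with an estimated correlation, unadjusted 0.145), including the transcription factor genes Myc at -0.25 (SE 0.10) and Etv1 at -0.36 (SE 0.19), the ERK phosphatase gene Dusp6 at -0.29 (SE 0.13) and the feedback inhibitor gene Spry4 at -0.30 (SE 0.17), at adjusted p = 0.673 to 0.699. A second probe set gave -0.15 for Etv1, at nearly the same brightness, and -0.03 for Dusp6, under the filter, and Spry4 was at -0.10 without high-fat diet replicate 1. In these last 3 lists, 0 members passed when adjusted over the list alone in limma, against 0, 5 and 2 at an unadjusted p under 0.05 and 0 without moderation.

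**Figure D2:**
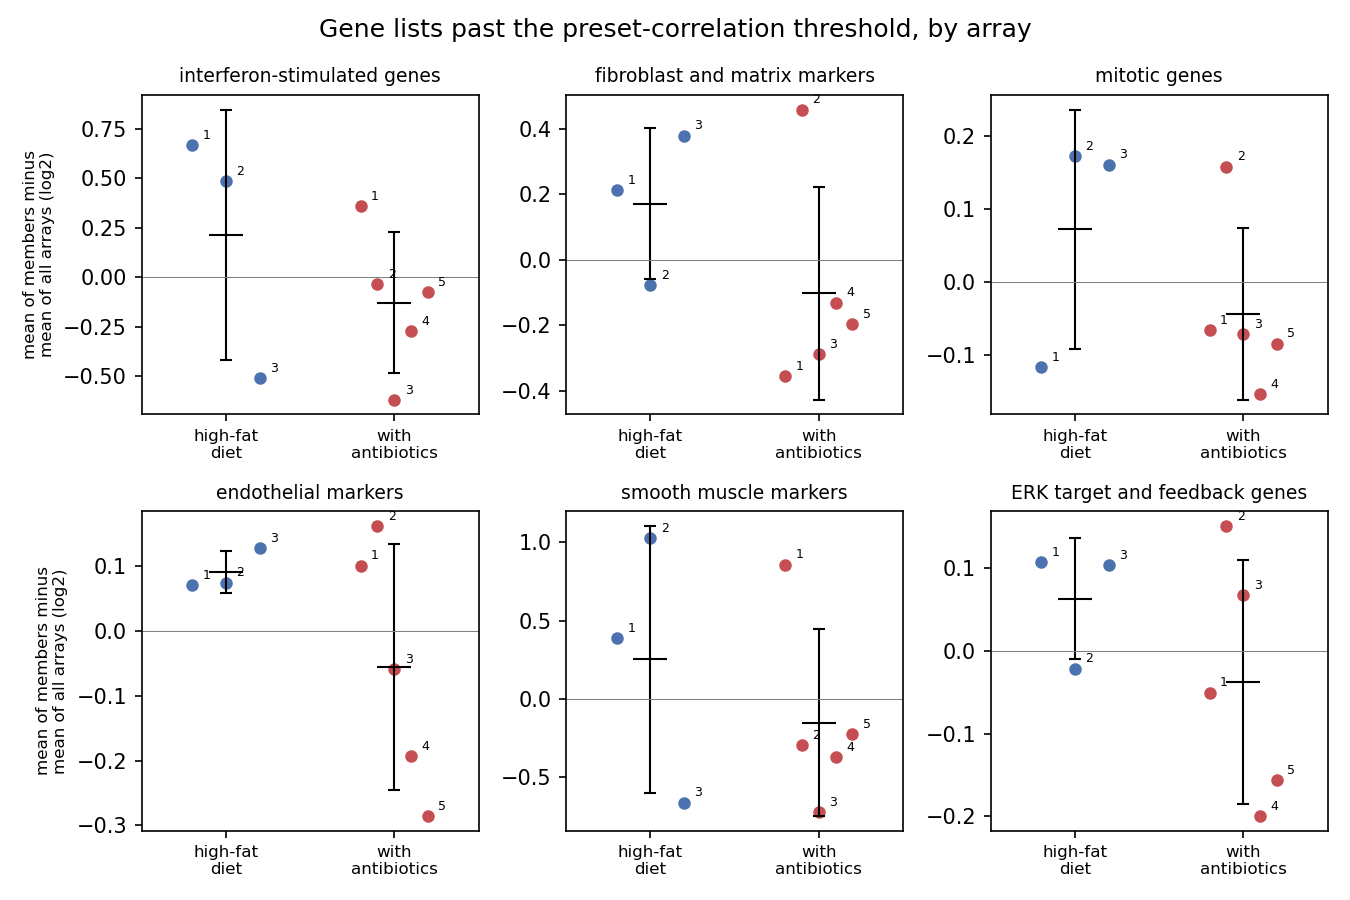
Mean log2 value of each list's members on each array (points, numbered by replicate), centred on the mean of the 8 arrays, for the 6 lists past camera's preset-correlation threshold, with the mean and SD of each group as bars. The groups overlapped in every list shown; interferon-stimulated genes ranged from -0.62 to 0.66.

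Each of these 6 calls was lost with an estimated correlation and with fry (adjusted p = 0.985 each), and 0 of 46 lists had an unadjusted p under 0.05 by either. In the preset test 8 of 46 lists had an unadjusted p under 0.05. Leaving out single arrays also ended calls. The interferon call ended without high-fat diet replicate 1 (mean -0.12, adjusted p = 0.383), the fibroblast call without high-fat diet replicate 3 (-0.17, adjusted p = 0.0699), and the mitotic call without high-fat diet replicate 2 (-0.07, adjusted p = 0.161) or 3 (-0.07, adjusted p = 0.0940). The endothelial call ended without high-fat diet replicate 3 (-0.13) or antibiotic replicate 4 (-0.11) or 5 (-0.09), at adjusted p = 0.0693 to 0.108. The smooth muscle call ended without high-fat diet replicate 1 (-0.33) or 2 (-0.02) or antibiotic replicate 2 (-0.37), 3 (-0.26) or 4 (-0.35), at adjusted p = 0.0530 to 0.624. The ERK call ended without high-fat diet replicate 1 (-0.08) or 3 (-0.08) or antibiotic replicate 1 (-0.10), 4 (-0.06) or 5 (-0.07), at adjusted p = 0.0515 to 0.247. Without high-fat diet replicate 3, the interferon mean was -0.70 and the smooth muscle mean -0.86. The interferon mean was -0.21 without high-fat diet replicate 2 and -0.22 without antibiotic replicate 3, the mitotic mean -0.21 without high-fat diet replicate 1, the fibroblast mean -0.41 without antibiotic replicate 2 and the smooth muscle mean -0.65 without antibiotic replicate 1, all past the threshold.

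Epithelial and secretory genes did not pass in any list. All 13 luminal markers tested were slightly higher with antibiotics, by 0.10 on average (camera adjusted p = 0.316), or by 0.05 without high-fat diet replicate 1 and 0.04 without the 3 arrays highest in skeletal muscle markers, with the pioneer factor gene Foxa1 at 0.26 (SE 0.12), the adhesion molecule gene Epcam at 0.15 (SE 0.08) and the keratin gene Krt8 at 0.08 (SE 0.09), at adjusted p = 0.676 to 0.844. Foxa1 was at 0.16 without high-fat diet replicate 1 and Krt8 at 0.03 without antibiotic replicate 1. Ly6d and Krt4, markers of progenitor-type luminal cells, were higher by 0.25 and 0.37, and the basal keratin gene Krt15 by 0.53 (adjusted p = 0.673 to 0.699), but Krt4 and Krt15 were low on high-fat diet replicate 3 and differed by 0.09 and 0.13 without it. As lists, progenitor-type luminal markers differed by 0.05 on average, 7 higher and 2 lower (camera adjusted p = 0.757). Basal markers differed by 0.14 on average (median 0.03), 6 higher and 3 lower (camera adjusted p = 0.692). Prostate secretory genes were lower by -0.25 on average, 9 of 16 lower (camera adjusted p = 0.513), and varied widely. Their mean was past the threshold without high-fat diet replicate 1 (-0.56, adjusted p = 0.0478), without the 3 arrays highest in skeletal muscle markers (-0.77, adjusted p = 0.000787) and with the fibroblast mean as a covariate (-0.67, adjusted p = 0.0103), and was 0.07 without high-fat diet replicate 2. Pbsn, which encodes probasin, was at 6.38 ± 2.02 (SD, n = 3) and 5.18 ± 1.56 (SD, n = 5), a difference of -1.20 (SE 1.02, adjusted p = 0.777). The transglutaminase gene Tgm4 and Msmb differed by -1.55 and -1.10, and the spermine-binding protein gene Sbp by 0.73 (adjusted p = 0.730 to 0.801). Single arrays moved these values widely: Pbsn differed by -0.30 and Tgm4 by -0.01 without high-fat diet replicate 2, Msmb by -0.20 without high-fat diet replicate 3 and Sbp by 0.17 without high-fat diet replicate 1. In the other direction, Pbsn, Tgm4 and Msmb differed by -2.30, -2.51 and -1.83 without high-fat diet replicate 1. Sbp differed by 1.28 without high-fat diet replicate 3. Among androgen-responsive genes, members went opposite ways, Sgk1 at -0.35 (SE 0.15) and Steap4 at 0.47 (SE 0.22), both at adjusted p = 0.673.

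Apart from the interferon-stimulated genes, immune and microbial lists did not pass in the reported fit. With the fibroblast mean as a covariate, the MHC class II, NF-kB target, IL-6 and STAT3 target, and complement and coagulation lists did pass camera's preset threshold. Inflammatory cytokines and enzymes were higher by 0.14 on average (camera adjusted p = 0.972), but lay at -0.04 without high-fat diet replicate 2, with the neutrophil chemokine gene Cxcl5 at 0.80 (SE 0.32) and the nitric oxide synthase gene Nos2 at 0.71 (SE 0.41). The neutrophil marker Ly6g was lower on all 5 antibiotic arrays than on the other 3 (log2 difference -0.95, SE 0.28, exact permutation p = 0.0357), but the neutrophil list did not lean the same way, with 9 of 14 members higher and a mean of 0.01 (camera adjusted p = 0.838), although it passed without high-fat diet replicate 2 (-0.45, adjusted p = 0.00336). Foxp3, the transcription factor of regulatory T cells, differed by 0.48 (SE 0.20) and Prf1, which encodes perforin, by -0.29 (SE 0.11). T and NK cell markers as a list had 7 members higher and 7 lower (camera adjusted p = 0.838). The macrophage gene Gpnmb differed by -0.55 (SE 0.24), or by -0.21 without high-fat diet replicate 3. The macrophage list did not lean the same way, with 9 of 14 members higher and a mean of -0.01 (camera adjusted p = 0.938). Mast cell genes were lower for 8 of 9, by -0.36 on average (camera adjusted p = 0.257), and passed without high-fat diet replicate 3 (-0.61) or antibiotic replicate 1 (-0.55) but lay at 0.01 without high-fat diet replicate 1, with the protease genes Cma1 at -0.64 (SE 0.38) and Tpsb2 at -0.69 (SE 0.43) lower and Kit at 0.46 (SE 0.17) higher. Without high-fat diet replicate 1, Cma1 and Tpsb2 were at -0.31 and -0.30. Antimicrobial and mucosal defence genes were higher for 10 of 13, by 0.37 on average (camera adjusted p = 0.407), and passed without high-fat diet replicate 3 (0.73, adjusted p = 0.00255), without the 2 arrays lowest in seminal vesicle genes (0.73, adjusted p = 0.000984) and with the fibroblast mean as a covariate (0.61, adjusted p = 0.0312), but lay at 0.15 (adjusted p = 0.962) without high-fat diet replicate 2 and at 0.22 (adjusted p = 0.734) without high-fat diet replicate 1. Members included Duox2, a hydrogen peroxide-producing oxidase, at 1.21 (SE 0.61) and the lectin gene Reg3b at 0.81 (SE 0.53). Duox2 and Reg3b were at 0.72 and 0.05 without high-fat diet replicate 2, and at 2.12 and 1.37 without high-fat diet replicate 3. In the unfolded protein response, 11 of 15 genes were higher, by 0.08 on average (camera adjusted p = 0.407), a mean difference that was 0.01 without high-fat diet replicate 1 (adjusted p = 0.876) and 0.15 without high-fat diet replicate 2 (adjusted p = 0.125), with the chaperone genes Hspa5 at 0.22 (SE 0.10) and Dnajc3 at 0.33 (SE 0.13) and with Creld2 at 0.30 (SE 0.11). The short-chain fatty acid receptor gene Ffar2 was near the filter at 4.05 ± 0.06 (SD, n = 3) and 3.91 ± 0.09 (SD, n = 5). Adjusted p-values of the genes in this paragraph lay between 0.673 and 0.729. Il6 (2.08 and 2.19) and Ffar3 (2.91 and 3.00) were under the filter of 3.82 and were not tested.

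The lists not past the threshold numbered 40, of which camera placed 16 higher and 24 lower, with adjusted p-values from 0.216 upward. Camera's direction differed in sign from the mean for 4 of these (adipocyte, neutrophil, T and NK cell, and hypoxia lists). It differed from the median for 7 (androgen-responsive, adipocyte, macrophage, neutrophil, circadian, NRF2, and complement and coagulation lists).

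**Figure D3:**
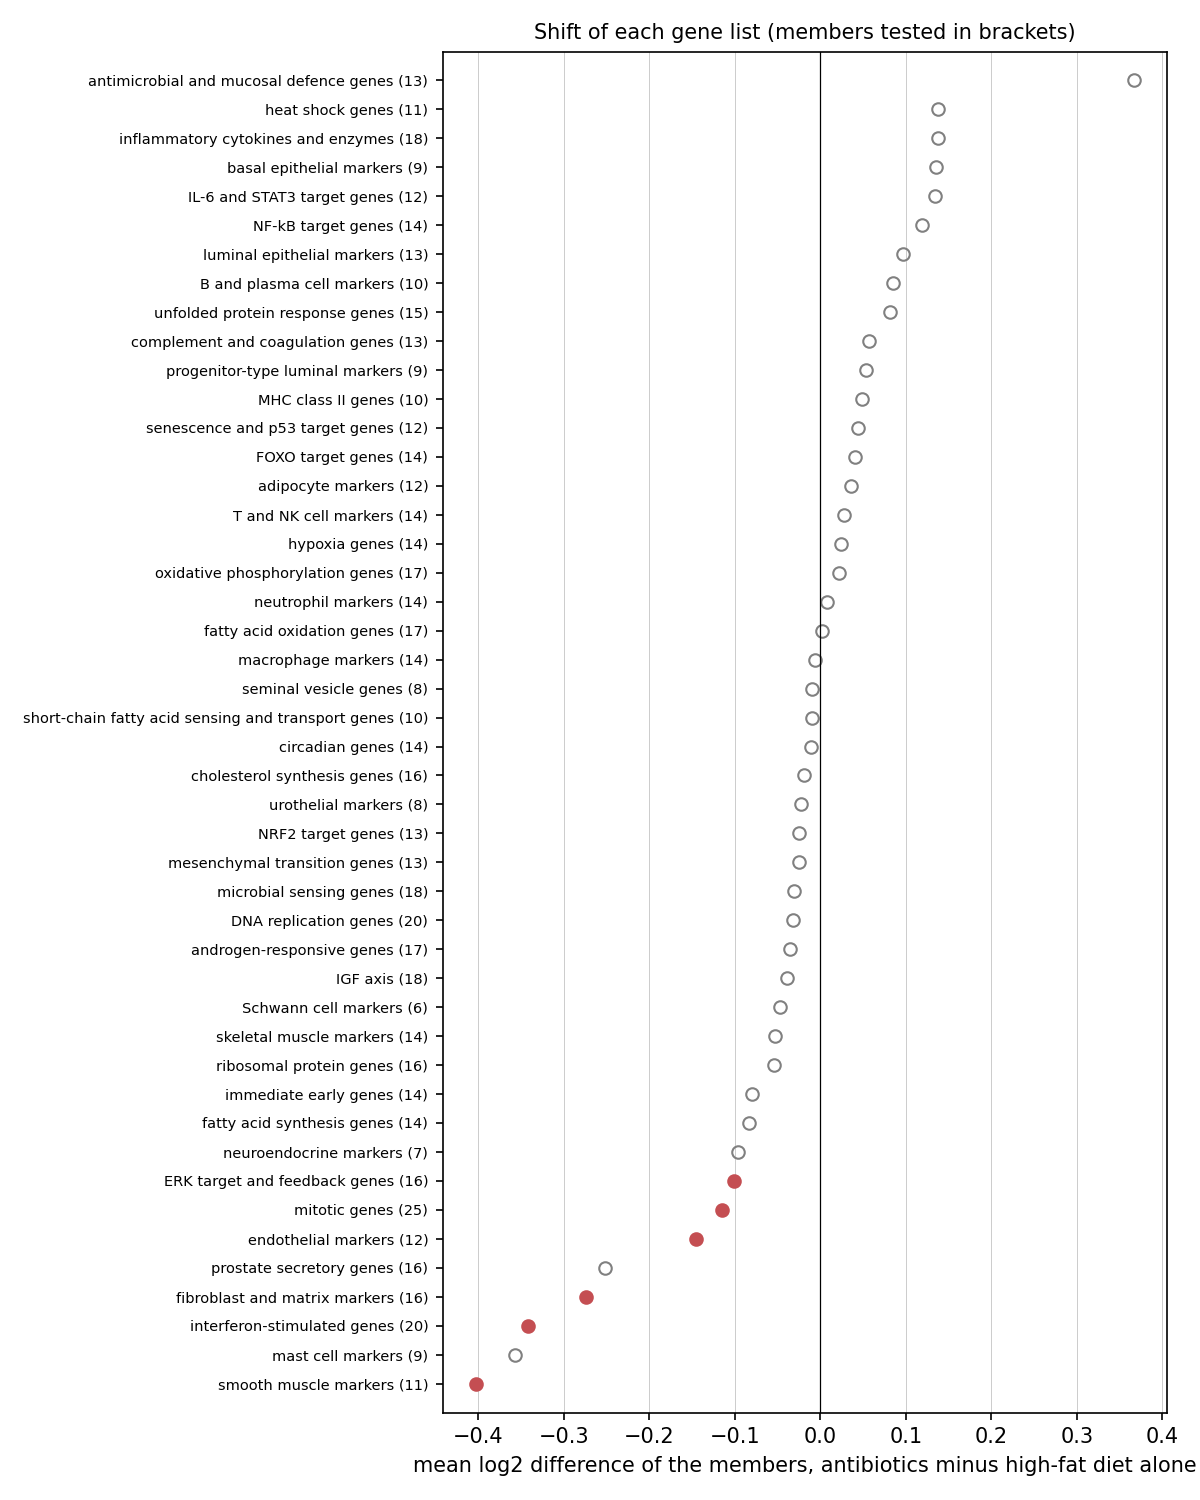
Mean log2 difference of the tested members of each of the 46 gene lists, antibiotics minus high-fat diet alone (horizontal axis), ordered by size. Filled points mark the 6 lists past camera's preset-correlation threshold, which lay at -0.10 to -0.40; open points did not pass.

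Markers of adjacent tissues differed between arrays far more than between groups. Seminal vesicle genes spanned 7.25 on the log2 scale (153-fold), lowest on high-fat diet replicate 3 (-4.41) and antibiotic replicate 3 (-3.44) and highest on high-fat diet replicate 2 (2.84). Skeletal muscle markers spanned 2.75 (6.74-fold) and were high on high-fat diet replicate 1 (1.08) and antibiotic replicates 1 (1.69) and 4 (1.36). Neither list passed between the groups (camera adjusted p = 0.869 and 0.763), but seminal vesicle genes did without high-fat diet replicate 3 (-2.22, adjusted p = 0.00310). Smooth muscle markers, which spanned 1.75, were high on high-fat diet replicate 2 (1.03) and antibiotic replicate 1 (0.86). With the seminal vesicle and skeletal muscle means as covariates, Igf1 differed by -0.60 (SE 0.16) and Epyc by -1.51 (SE 0.11, adjusted p = 0.0196). With the fibroblast and matrix mean as the covariate instead, Igf1 differed by -0.46 (SE 0.16) and Epyc by -1.41 (SE 0.13), and Epyc was not past the threshold (adjusted p = 0.0716). In that fit the mitotic (-0.06), endothelial (-0.08) and ERK (-0.03) calls also ended, at adjusted p = 0.0973 to 0.323. With the seminal vesicle and skeletal muscle covariates the ERK call ended (mean -0.10, adjusted p = 0.0548), the other 5 calls were made, and the mast cell list passed (-0.34, adjusted p = 0.0229). Without the 2 arrays lowest in seminal vesicle genes, the interferon and smooth muscle calls were made and those of the fibroblast (-0.12), mitotic (-0.06), endothelial (-0.13) and ERK (-0.11) lists were not. Without the 3 arrays highest in skeletal muscle markers, the fibroblast (-0.16, adjusted p = 0.0597) and ERK (-0.02, adjusted p = 0.433) calls ended and the other 4 were made.

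**Figure D4:**
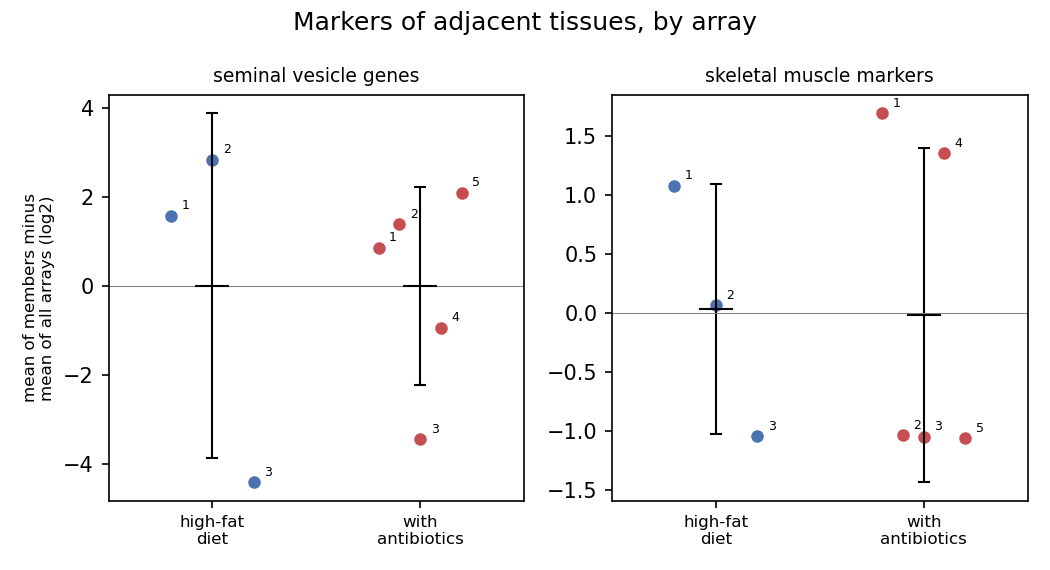
Mean log2 value of seminal vesicle genes and skeletal muscle markers on each array (points, numbered by replicate), centred on the mean of the 8 arrays, with the mean and SD of each group as bars. High and low arrays occurred in both groups, and seminal vesicle genes ranged from -4.41 to 2.84.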

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

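The tests on small nuclear RNAs, on microRNA genes, on the host genes without Snhg11 and on the red cell genes without Car1 were chosen after the result was seen, and the 3 patterns weighed were noticed in the data.

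Among the 80 genes and 16 list means of the text, 7 had 1 antibiotic array standing far from the other 4, where chance at 1 in 20 would give about 5. These genes and means are not independent of each other. The gap to the nearest array was 0.769 of the group's range for Zfp773 (highest on antibiotic replicate 4, 5.14 against 4.85). It was 0.802 for Fap (5.24 against 4.54), 0.723 for the mean of the fibroblast and matrix markers and 0.719 for the mean of the mitotic genes, each highest on antibiotic replicate 2. It was 0.719 for Actg2 (8.28 against 7.45), 0.774 for Des (9.22 against 7.98) and 0.799 for Tpsb2 (6.70 against 5.31), each highest on antibiotic replicate 1.

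Igf1 was lower in the antibiotic arrays, as was the fibroblast and matrix list. With the mean of that list as a covariate, the Igf1 difference went from -0.60 (SE 0.16) to -0.46 (SE 0.16), still more than 2 standard errors from 0. The list mean therefore did not account for the whole difference. A mean of 16 marker genes measures the stromal share imperfectly, and smooth muscle and endothelial means were not entered. A lower stromal share thus stays open as a part or the whole of the cause. With the seminal vesicle and skeletal muscle means as covariates the Igf1 difference was -0.60 (SE 0.16), also more than 2 standard errors from 0. The means of these lists hardly differed between the groups (-0.01 and -0.05). That fit could therefore hardly move the Igf1 difference, and it cannot decide on uneven amounts of these tissues. Neither fit took Igf1 past the adjusted threshold (adjusted p = 0.666 and 0.578). An effect of the antibiotics on Igf1 expression may remain as a hypothesis, as may chance among the genes tested.

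Small nucleolar RNAs, guides of RNA modification, were lower for 69 of 77 genes, by -0.32 on average (SE over genes 0.03; camera adjusted p = 9.19e-21; adjusted p = 0.348 with an estimated correlation; -0.34 under quantile normalization and under centring; exact permutation p of the array means 0.0536). Host genes were represented by 15 genes, Zfas1 and genes named Snhg, which were not matched to these 77 RNAs. They differed by -0.0631 (SE over genes 0.0732, median -0.11, 11 of 15 lower, camera adjusted p = 0.0189, adjusted p = 0.449 with an estimated correlation). Without Snhg11, named for being farthest from 0 (0.78, SE 0.43, adjusted p = 0.699), they differed by -0.123 (SE 0.0447). Lower transcription of these 15 hosts therefore cannot be told apart from no change, since 1 of 15 genes decides on which side of 2 standard errors the mean lies. Whether the hosts of the 77 RNAs changed was not tested. The standard error over genes does not measure the spread between mice. By array, the host means overlapped between the groups (exact permutation p of the array means 0.607). Other short nuclear RNAs were lower by -0.377 on average over 5 probe sets (SE over probe sets 0.185, just over 2 standard errors). As the class was first defined, they were lower by -0.432 (SE 0.145) over 8 probe sets. U3 and other nucleolar RNAs were then taken out of it with that value known. Lower recovery of RNA of such lengths in extraction or labelling predicted such a mean. The spread over probe sets does not measure the spread between mice, so the result cannot decide on lower recovery. MicroRNA genes, whose probe sets may read longer transcripts, differed by -0.07 (SE over genes 0.01, 130 of 192 lower, camera adjusted p = 0.000964, adjusted p = 0.449 with an estimated correlation). They were lower too, but by less than the small nucleolar RNAs, so a loss of like size in every short RNA is not shown. An effect of the antibiotics on these RNA classes stays open and untested.

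Beside Slc4a1 (-0.94, or -0.57 without high-fat diet replicate 1), all 4 probe sets above the filter that list only globin genes were lower, by -0.74, -1.44, -1.63 and -1.89, with no overlap between the groups (exact permutation p = 0.0179 each, the smallest possible, unadjusted). Further red cell genes differed by -0.11 on average (SE over genes 0.05, median -0.06, 13 of 16 lower; camera adjusted p = 0.0189; adjusted p = 0.449 with an estimated correlation), and their array means overlapped (exact permutation p = 0.304). Without Car1, a red cell carbonic anhydrase gene named for being farthest from 0 (-0.65, SE 0.55, adjusted p = 0.777), their mean was -0.0765 (SE 0.0293). Both means lay more than 2 standard errors below 0, as predicted for fewer red cells or their precursors in the tissue. These standard errors are over genes and do not measure the spread between mice. The second mean also lay above the bound of -0.1 set in advance against that explanation, by less than its standard error. The first lay above that bound under quantile normalization (-0.0901) but not under centring (-0.134). Fewer red cells or precursors therefore stay open and are not shown by these genes. Platelet genes differed by -0.17 (SE over genes 0.13, 7 genes), so less whole blood left in the tissue cannot be told apart from a difference in red cells alone, the spread over platelet genes being too wide.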

How the results depend on the processing

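The fits with tissue or fibroblast covariates and without arrays chosen by adjacent tissue were chosen after seeing the data; the rest were planned. Of 80 genes and 16 lists in the text, 76 genes and 9 lists kept their direction under every alternative run, and of these 80 genes Epyc alone passed under any of them. The count of genes changed was 1, Epyc, under quantile normalization, centring, both other filters, the mean of probe sets, trend and robust, array weights and a threshold of 0.10. It was 0 without moderation, 0 to 1 leaving out each array in turn, 2 with the seminal vesicle and skeletal muscle covariates (Epyc and Vnn3, the latter named after its values were seen), and 0 in limma with the fibroblast covariate and without the 3 arrays highest in skeletal muscle or the 2 lowest in seminal vesicle genes. The 127 genes at an unadjusted p under 0.05 and 1.5-fold became 80 with the filter at the 50th percentile, where fewer genes were tested, 199 with array weights, 69 without moderation, 250 with the fibroblast covariate, 261 without those 3 arrays and 297 without those 2, and 106 to 360 leaving out each array in turn (360 without high-fat diet replicate 3, 272 without antibiotic replicate 1). The 6 lists became 0 with an estimated correlation, 0 with fry, 10 with the fibroblast covariate, 10 without those 3 arrays (the skeletal muscle list, which chose them, among the 10), and 3 to 9 leaving out each array in turn (3 without antibiotic replicate 4, 9 without antibiotic replicate 1). They were 5 with centring and 5 with no filter, where the ERK call ended (adjusted p = 0.0556 and 0.164), and 7 with the mean of probe sets, where the ribosomal protein list was gained. The cause was not tested.

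With the replicate number as a replicate block over 6 arrays, 0 genes passed (157 at an unadjusted p under 0.05 and 1.5-fold, 78 higher and 79 lower) and 4 lists. The mitotic (-0.07, adjusted p = 0.104), endothelial (-0.02, adjusted p = 0.577) and ERK (-0.01, adjusted p = 0.661) calls ended there, and mast cell markers passed (-0.20, adjusted p = 0.0206). Deviations of same-numbered arrays correlated at 0.14, -0.08 and 0.47, and high-fat diet replicate 2 correlated better with antibiotic replicate 1 (0.36), so the numbers were not taken as pairs.

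The difference of Igf2 reversed to 0.162 without the 2 arrays lowest in seminal vesicle genes and ran from -0.245 to 0.0881 leaving out each array. Msmb reversed to 0.426 without the same 2 arrays and Krt8 to -0.0158 without the 3 highest in skeletal muscle. The IGF axis mean was 0.0126 with the fibroblast covariate, and a list has no value where its own mean is a covariate or chose the arrays left out. Neutrophil markers were at -0.0137 with centring, -0.0387 with no filter and -0.00317 with the tissue covariates, and seminal vesicle genes at 0.801 without the 3 arrays highest in skeletal muscle. Leaving out each array, Mki67 ran from -0.00993 to 0.229, mast cell markers from -0.606 to 0.00686, prostate secretory genes from -0.564 to 0.0742 and inflammatory cytokines from -0.0419 to 0.344, neutrophil markers from -0.446 to 0.419, seminal vesicle genes from -2.22 to 1.41 and skeletal muscle markers from -0.592 to 0.470. None of these passed a threshold in the reported fit. Of the 80 genes, 31 were over 1.5 times smaller or reversed without 1 array, 29 of them without a high-fat diet array. Signal over background was not given, so the limit it sets for dim genes is unknown.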

Other observations

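The tests of gene families and of probe sets without a single gene symbol were chosen after the data were seen.

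Of 17 gene families looked through by name, 9 passed camera's threshold at its preset correlation, and 0 passed with an estimated correlation in camera (2 at an unadjusted p under 0.05), so the preset test separated little here. Zinc finger genes named Zfp were higher with antibiotics for 237 of 324, by 0.09 on average (adjusted p = 0.00634; adjusted p = 0.449 with an estimated correlation), and by 0.10 and 0.07 under quantile normalization and centring. Of 7 secretoglobin genes, 5 were higher and 2 lower, with a mean of 1.51 (camera adjusted p = 0.285; exact permutation p of the array means 0.107). Their mean was high on antibiotic replicates 3 (2.46) and 5 (1.38) and low on antibiotic replicate 2 (-1.11), close to high-fat diet replicates 1 (-1.12) and 2 (-1.10).

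The 17824 probe sets without a single gene symbol held 0 past the adjusted threshold in limma (smallest adjusted p 0.714), with 1048 at an unadjusted p under 0.05 against 891.2 expected by chance. The spread around that number was not measured for these probe sets.

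Chance could not be excluded for any of these counts. Of the 56 splits of the 8 arrays into 3 and 5, 9 gave at least 1 gene past the adjusted threshold, the real one included, with 152 as the highest of the others. For genes at an unadjusted p under 0.05 and 1.5-fold, 18 splits gave at least the real 127, with 572 as the highest of the others, and for genes at an unadjusted p under 0.05 alone, 8 splits gave at least the real 1216, with 2423 as the highest. For gene lists past camera's preset threshold, 48 splits gave at least the real 6, with 30 as the highest and 13 as the median of the others. The split that set high-fat diet replicates 1 and 2 and antibiotic replicate 1 against the other 5 arrays gave both 152 and 572 genes, which points to a structure of the samples other than the groups. These 3 arrays lay together on the first principal component (-19.7, -26.9 and -21.0, 33.2% of the variance) and had the highest interferon-stimulated gene means (0.66, 0.49 and 0.36). They also had the highest smooth muscle means (0.39, 1.03 and 0.86) and the lowest antimicrobial and mucosal defence means (-0.52, -0.66 and -0.17). What underlies this structure was not tested.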
